A study of Arabidopsis thaliana with 12 samples.

How the data were processed

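RNA was measured by sequencing in whole seedlings of Arabidopsis thaliana, 12 days after germination, in Col-0 and in the mutants nrpb2-3, ssrp1-2 and spt16-2, with 3 libraries per genotype. Per the labels, seeds were kept 4 days at 4 °C and grown in soil at 21 °C, and total RNA was taken. The labels do not say whether replicates came from separate sowings, so the p-values measure the spread between these samples, which may be technical.

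The deposited count table holds counts per gene for 32833 genes, made by the authors with fastp 0.23.4 and HISAT2 2.2.1 on the genome build TAIR10, per the submitters' processing notes. The counting tool, its strand setting and its treatment of reads that map to several places are not stated. The deposited table that is called TPM holds a signal whose columns sum to 652500 to 1181500, which differs between libraries, unlike TPM. Within a library each value of that signal was the count over a gene length and a library factor (largest relative deviation 0.000717 over 14093 genes), so the authors rescaled it across libraries, and it was used as an alternative only. Gene names came from the TAIR10.1 annotation, in which 32548 loci were found and 285 were not, 152 of them mitochondrial and 133 chloroplast loci, and no coordinates are given. Each library held 39483328 to 43434901 counts. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

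Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a minimum count of 10, and a robust quasi-likelihood fit of all 12 libraries with the genotype as the single factor. Of 26456 genes with a count in any library, 20471 were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, in 5 comparisons: each mutant with Col-0, spt16-2 with ssrp1-2, and nrpb2-3 with the mean of ssrp1-2 and spt16-2. Fold changes are log2 with the SE of the fit, and levels are scaled CPM with the SD over 3 libraries. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group, and where it had 1 to 3 counts it is a ratio with a 95% counting interval.

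A set of 25 gene lists (439 entries) was written from general knowledge of the field before the data were examined, as were the comparisons, tests, named-gene rule and first alternatives. The lists were photosynthesis, flavonoid and anthocyanin synthesis, RNA-directed DNA methylation, abscisic acid and cold, cell cycle and DNA replication, DNA damage, shoot meristem, microRNA targets, heat shock, transcript elongation factors, core histones, salicylic acid defence, microRNA biogenesis, floral promoters, FLC clade repressors, root markers, ribosome biogenesis, auxin, floral organ identity, wounding and touch, H2A.Z and SWR1, Pol II subunits, jasmonate, circadian clock and seed maturation. Lists with at least 3 tested members were tested with camera (limma 3.58.1) on voom values, with a preset correlation of 0.01 and adjustment over the lists of a comparison, and again with the correlation estimated. With the preset correlation, other groupings of the same libraries called a median of 6 to 10 lists. A call with the preset correlation alone thus does little to tell the real grouping from another. fry, which asks whether members move one way on balance and compares them with no other genes, called 14, 5, 4, 1 and 13 lists in the 5 comparisons.

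Genes are named by a rule with 4 parts. The first is the 3 mutated genes. The second is, against Col-0, the 8 called genes with the largest log2 fold change in each direction (5 in the other comparisons), with a mean of at least 50 counts in the higher group and no overlap of CPM between groups. Of unchanged genes 10% have no such overlap by chance with 3 against 3. The third is, from each list, up to 4 called members with the smallest adjusted p, and any member to say that it was not called. The last is, of genes called alike in all 3 mutants, 5 in each direction. Of 155 genes the rule gave, 33 overlap another annotated gene, 21 of them a tested one, so with an unknown strand setting their counts may hold reads of the partner. Of the genes the rule gave, those in the text with a tested partner are SSRP1, RCA, SEP1, CYCD3;1 and INO80, and those with an untested one FLC, GMI1, SPL9 and EBP1. Counts of families with close paralogs (RBCS, histones, PDF1.2) depend on the unstated treatment of shared reads.

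The alternatives chosen then were median-of-ratios (RLE) size factors, DESeq2 1.42.0, limma-trend on log2 of the authors' scaled TPM plus 1 (at least 1 in 3 libraries), no filter on low counts, the libraries of the groups compared alone, the replicate number as a block, organelle genes left out, a fold threshold of 2, an estimated list correlation, and each library left out in turn (given for the libraries of the groups compared unless said otherwise). Library totals with no factor and removal of a trend with transcript length were added after seeing the data. Replicate numbers were read as pairs where the deviations from the group mean correlated above 0.1 in each pair of libraries with a shared number: spt16-2 with Col-0 (0.12, 0.35 and 0.31), spt16-2 with ssrp1-2 (0.20, 0.34 and 0.29). The same held for nrpb2-3 with ssrp1-2 (from 0.22) and with spt16-2 (from 0.14). All calls come from the fit without pairs unless a replicate block is named.

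Shared calls and correlations of fold changes were set beside 20 simulations of unchanged groups that share the controls. The test was also tested on simulated data made from these counts: of genes changed 2-fold it recovered 65.7%, 65.7% and 64.2% in the comparisons with Col-0. Of genes changed 1.5-fold it recovered 14.9%, 16.4% and 19.4%. Few genes were changed there (67 by 1.5-fold and 67 by 2-fold). The shares recovered thus do not describe nrpb2-3, where 30.9% of the genes tested were called. False calls over all simulated folds were 8, 3 and 7. DESeq2 made 33, 21 and 42 false calls there.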

Results

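Transcripts were counted in whole Arabidopsis thaliana seedlings taken 12 days after germination, in the wild type Col-0 and in 3 mutants, with 3 libraries per genotype and 12 in all. The mutants ssrp1-2 and spt16-2 each affect 1 of the 2 subunits of FACT, a histone chaperone that takes nucleosomes apart and rebuilds them as RNA polymerase II (Pol II) passes. The mutant nrpb2-3 affects the second-largest subunit of Pol II itself. By its title, the series is about how FACT is brought to genes and what the histone variant H2A.Z does there, and the RNA libraries address what each mutant does to transcript levels. Each library held 39483328 to 43434901 counts over 21516 to 23417 genes with at least 1 count. The nrpb2-3 libraries stood apart from the rest on the first principal component (42.4% of the variance), at 64.1 to 97.9 against −42.1 to −16.7 for the other 9 libraries. Col-0 replicate 1 lay at the far end of the second, at 60.7 against at most 34.4 in the others. It also held 1.23% of its counts in rRNA genes (95% Wilson interval 1.23 to 1.23) and 0.474% in organelle genes (0.472 to 0.476), each more than 2 times the share in any other library. This library enters every comparison with Col-0. Genes of photosynthesis took 21.3% ± 1.63 (SD, n = 3) of all counts in Col-0, 12.9% ± 3.25 in nrpb2-3, 20.1% ± 1.45 in ssrp1-2 and 19.4% ± 2.72 in spt16-2. All levels are scaled CPM (mean ± SD, n = 3). All fold changes are log2 ± SE from edgeR's quasi-likelihood fit, and all adjusted p-values of genes come from that test.

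The mutated genes were read first, as a check of the labels. Transcripts of SSRP1 (AT3G28730), the smaller FACT subunit, fell in ssrp1-2 from 43.8 ± 4.73 to 19.4 ± 1.39 CPM (log2 fold change −1.17 ± 0.11, adjusted p = 0.00046). Transcripts of SPT16 (AT4G10710), the larger subunit, stood at 53.8 ± 8.60 CPM in Col-0 and 37.7 ± 15.4 CPM in spt16-2, a difference that did not pass the test (log2 fold change −0.51 ± 0.22, adjusted p = 0.54). The 3 spt16-2 libraries did not match each other for this gene: replicates 1 and 3 lay below every Col-0 library (replicate 1 at 27.8 CPM), and the library labelled spt16-2 replicate 2 held 55.4 CPM, a level within the wild-type spread. Without the library labelled spt16-2 replicate 2, SPT16 was called lower than in Col-0 (adjusted p = 0.029, the smallest of its alternatives, which ran up to 0.82). That library thus goes against its label at the mutated gene and enters each direction given here for spt16-2. In the reciprocal mutants, SPT16 stood at 80.7 ± 4.87 CPM in ssrp1-2 (adjusted p = 0.38) and SSRP1 at 52.0 ± 4.40 CPM in spt16-2 (adjusted p = 0.58), and neither was called different from Col-0. In nrpb2-3, transcripts of NRPB2 (AT4G21710) itself rose from 42.3 ± 5.43 to 67.1 ± 1.96 CPM (0.67 ± 0.12, adjusted p = 0.0013), so its level neither checks nor contradicts that label. SSRP1 also rose in nrpb2-3 (0.50 ± 0.11, adjusted p = 0.0048), and SPT16 did not pass the test there (0.49 ± 0.22, adjusted p = 0.10). SPT16 was called higher there with a replicate block (0.026) and in a fit on the 6 libraries alone (0.043).

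**Figure D1:**
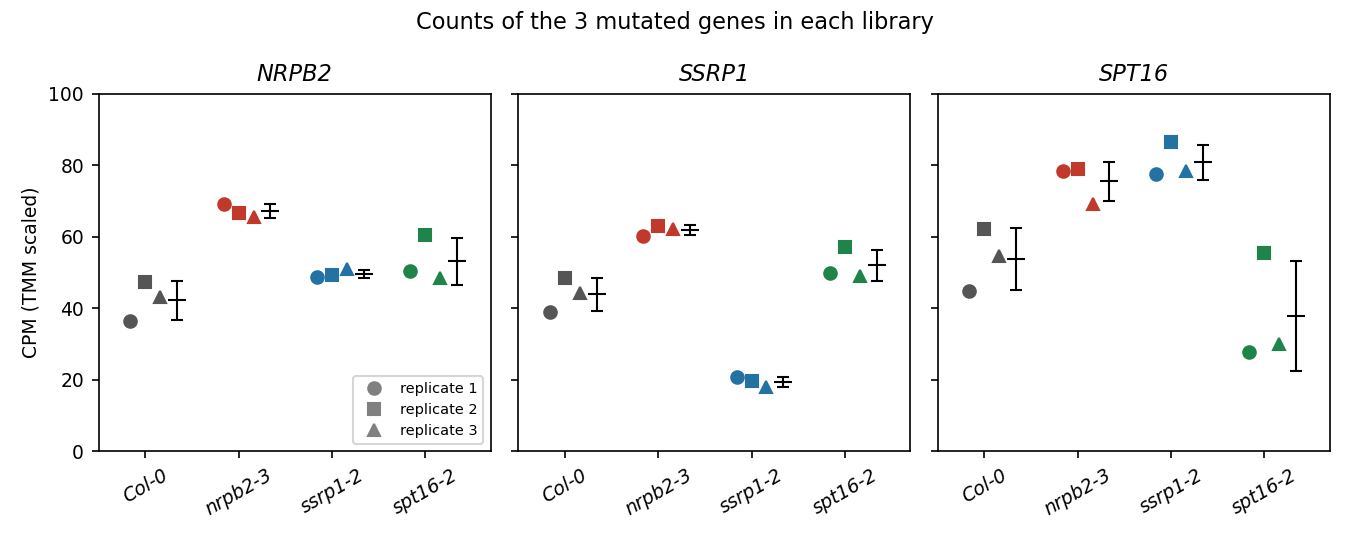
Transcript levels of the 3 mutated genes in each library, in scaled CPM on a linear axis, with points for libraries and bars for mean and SD (n = 3). SSRP1 is lowest in ssrp1-2 (19.4 ± 1.39 CPM), and the library labelled spt16-2 replicate 2 holds 55.4 CPM of SPT16 against 27.8 CPM in replicate 1.

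The comparison of nrpb2-3 with Col-0 addressed which transcripts depend on an intact Pol II. Single flowering genes passed the test here, and none of the 3 flowering lists passed the list test against all other genes. fry, which compares members with no other genes, called floral promoters lower (adjusted p = 0.00085) and the FLC clade higher (0.026). FLC (AT5G10140), a MADS-box repressor of flowering, rose from 0.562 ± 0.478 to 7.21 ± 1.06 CPM (log2 fold change 3.67 ± 0.74, adjusted p = 0.0038), and FT (AT1G65480), the mobile flowering signal, fell from 2.91 ± 1.13 to 0.278 ± 0.235 CPM (−3.38 ± 0.55, adjusted p = 0.00080). The floral integrators SOC1 (AT2G45660, −1.84 ± 0.25) and AGL24 (AT4G24540, −2.28 ± 0.14) fell as well, and AG (AT4G18960), which specifies stamens and carpels, fell from 1.52 ± 0.620 to 0.0273 ± 0.0473 CPM (−5.74 ± 0.68, adjusted p = 0.00011). AP1 (AT1G69120), which starts floral meristems, had 1 count over the 3 nrpb2-3 libraries, and the ratio of Col-0 to nrpb2-3 was 88.4 (95% counting interval 15.3 to 3549.8). By lists, 5 of 11 floral promoters were lower and 1 higher (5 and 1 adjusted over the list alone), a list that missed the threshold of the list test (median log2 fold change −0.79, adjusted p = 0.052). That list was called when genes with low counts were kept (adjusted p = 0.034) and without Col-0 replicate 1 (0.040), Col-0 replicate 2 (0.037) or nrpb2-3 replicate 1 (0.038). Of 7 floral organ identity genes 2 were lower (2 adjusted over the list alone, where 1 was higher; median −0.40, list adjusted p = 0.28). Of the 6 FLC clade repressors 2 were higher (2 adjusted over the list alone; median 0.33, list adjusted p = 0.16). Leaving out 1 library moved some of these fold changes by more than 1.5 times with their calls kept. FLC was 4.37 without Col-0 replicate 2, FT −4.29 without nrpb2-3 replicate 2. AG was −5.15 without nrpb2-3 replicate 3. Without nrpb2-3 replicate 1 both AG and AP1 had 0 counts left in nrpb2-3, so no fold is given.

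Genes of the leaf's main work were lower in nrpb2-3 and genes of stress pigments, dividing cells and the shoot meristem higher. Of 27 nuclear photosynthesis genes, 25 fell and 0 rose (27 and 0 adjusted over the list alone, median −1.15). Among them were RBCS1A (AT1G67090) and RBCS1B (AT5G38430), small-subunit genes of Rubisco (−1.36 ± 0.23 and −1.74 ± 0.29), and RCA (AT2G39730), the activase of Rubisco (−1.43 ± 0.22). Most of the size of this fall is shared with transcripts outside the list that are as abundant, since random lists matched in expression had a median of −0.95. Only members of the list were left out of the random lists, so these may hold other photosynthesis genes. Of 14 flavonoid and anthocyanin genes, 12 rose and 0 fell (12 and 0 adjusted over the list alone; median 1.94), with the regulator TT8 (AT4G09820) at 2.85 ± 0.44 and the glycosyltransferase UF3GT (AT5G54060) at 3.17 ± 0.45. Of 7 shoot meristem genes 5 rose (6 adjusted over the list alone; median 2.16), among them the homeobox genes KNAT1 (AT4G08150, 2.33 ± 0.36) and KNAT6 (AT1G23380, 2.55 ± 0.35). Of 20 abscisic acid and cold genes 7 rose (7 adjusted over the list alone; median 0.83), with the stress reporter RD29A (AT5G52310) at 1.54 ± 0.13. Of 10 DNA damage genes 5 rose (7 adjusted over the list alone; median 0.91), with GMI1 (AT5G24280), induced by double-strand breaks, at 2.90 ± 0.29 and the transcription factor NAC044 (AT3G01600) at 2.07 ± 0.23. Of 16 genes of RNA-directed DNA methylation 11 rose (11 adjusted over the list alone; median 0.64), with RDR2 (AT4G11130), an RNA-dependent RNA polymerase, at 1.09 ± 0.18, and of 32 cell cycle genes 13 rose (17 adjusted over the list alone; median 0.51), with the cyclin CYCD3;1 (AT4G34160) at 1.36 ± 0.15. The list test against all other genes called these 7 lists (adjusted p = 1.7e-12 for photosynthesis, 8.9e-06 for flavonoids, 0.00053 for DNA methylation and 0.00071 for each of the other 4). None of the 7 calls held when the correlation between members was estimated (adjusted p = 0.53 with an estimated correlation for the cell cycle, 0.35 for each of the others). With no other genes to compare, fry called each of the 7 in the same direction, with an adjusted p of at most 0.037. Fold changes against Col-0 rose with transcript length in every mutant. The list test was not run with that trend removed, so no list call in any comparison was checked against it.

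The remaining lists of that comparison were called by smaller margins or not at all. Higher were microRNA targets (12 of 35 higher and 2 lower, 13 and 3 adjusted over the list alone, median 0.27, list adjusted p = 0.016). Among them were the flowering repressor TOE2 (AT5G60120) at 1.45 ± 0.14 and the copper superoxide dismutase CSD2 (AT2G28190) in the other direction at −1.90 ± 0.19. Heat shock genes (5 of 17 higher and 1 lower, 7 and 1 adjusted over the list alone, median 0.55, list adjusted p = 0.017) were also called higher, with the chaperone HSP70-4 (AT3G12580) at 1.60 ± 0.29. So were transcript elongation factors (6 of 16 higher, 6 adjusted over the list alone, median 0.28, list adjusted p = 0.024), with VIP4 (AT5G61150) of the PAF1 elongation complex at 0.53 ± 0.10. MicroRNA biogenesis was called higher (4 of 8, 4 adjusted over the list alone, median 0.39, list adjusted p = 0.042), with the methyltransferase HEN1 (AT4G20910) at 0.65 ± 0.17. Core histones (5 of 31 lower and 1 higher, 5 and 0 adjusted over the list alone, median −0.28, list adjusted p = 0.024) were called lower, with the H2A gene HTA5 (AT1G08880) at −0.56 ± 0.11. Salicylic acid defence was called lower (5 of 20 lower, 4 adjusted over the list alone, median −0.48, list adjusted p = 0.042), with the defence regulator PAD4 (AT3G52430) at −1.03 ± 0.20. With library totals as the scale, the medians of histones and salicylic acid defence turned to 0.26 and 0.08. With an estimated correlation none of these 6 lists was called (adjusted p = 0.35 for microRNA targets, 0.35 for heat shock, 0.35 for elongation, 0.53 for microRNA biogenesis, 0.64 for histones, 0.54 for salicylic acid). MicroRNA biogenesis lost its call without Col-0 replicate 1 (adjusted p = 0.15), nrpb2-3 replicate 1 (0.082) or nrpb2-3 replicate 2 (0.11). Salicylic acid defence lost it without Col-0 replicate 2 (0.075), nrpb2-3 replicate 1 (0.21) or nrpb2-3 replicate 2 (0.064). Both were lost with median-of-ratios size factors (0.053 each). Core histones lost it without Col-0 replicate 3 (0.098) or nrpb2-3 replicate 3 (0.056), and elongation factors without nrpb2-3 replicate 2 (0.058). Members of the H2A.Z and SWR1 list went both ways, with 3 of 13 higher and 1 lower (3 and 1 adjusted over the list alone, median 0.19, list adjusted p = 0.52). The H2A.Z gene HTA11 (AT3G54560) fell (−0.76 ± 0.16, adjusted p = 0.0039) and the remodeller INO80 (AT3G57300) rose (0.69 ± 0.15, adjusted p = 0.0041), while the H2A.Z genes HTA8 (AT2G38810, −0.27 ± 0.14, adjusted p = 0.16) and HTA9 (AT1G52740, −0.22 ± 0.18, adjusted p = 0.37) were not called. Of 15 Pol II subunits 3 were higher and 2 lower (median 0.09, list adjusted p = 0.55), with NRPB1 (AT4G35800), the largest subunit, at 0.99 ± 0.15.

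Auxin genes split, 3 higher and 5 lower of 15 (3 and 5 adjusted over the list alone, list adjusted p = 0.28), with GH3.5 (AT4G27260), which conjugates auxin, at 3.23 ± 0.31 and the auxin repressor IAA19 (AT3G15540) at −2.30 ± 0.25. Their median of −0.15 turned to 0.37 with library totals as the scale, as did those of floral organ identity (−0.40 to 0.17) and ribosome biogenesis (−0.26 to 0.28). Root markers (2 of 8 higher, median 0.71, adjusted p = 0.16), ribosome biogenesis (0 higher and 0 lower of 9, adjusted p = 0.25) and wounding and touch genes (0 and 0 of 12, median −0.71, adjusted p = 0.30) were not called as lists. Neither were jasmonate genes (1 of 16 lower, median 0.12 and mean −0.33, adjusted p = 0.77) and clock genes (1 of 19 higher, median 0.10, adjusted p = 0.90). Root markers were called when genes with low counts were kept (adjusted p = 0.047) and without nrpb2-3 replicate 2 (0.020), ribosome biogenesis without Col-0 replicate 1 (0.0019) and wounding genes without Col-0 replicate 3 (0.012). Seed maturation had 2 tested members of 19 and was not tested as a list. Of these DOG1 (AT5G45830) fell (−0.79 ± 0.17) and OLEO4 (AT3G27660) rose (1.11 ± 0.32, lost without Col-0 replicate 3, adjusted p = 0.065, or nrpb2-3 replicate 2, 0.11, and in a fit on the 6 libraries of these groups alone, 0.055).

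The single genes with the widest differences were of another kind. The lncRNA AT2G04735 had 0 counts in Col-0 and 10.7 ± 2.55 CPM in nrpb2-3, at least 379.6-fold higher against a floor of 3 counts over the group. AT2G14378 and AT5G45910 were at least 312-fold and 271-fold higher. AT5G03090 had 1 count over the Col-0 libraries and stood 2830.1 (95% counting interval 508 to 111810) times higher in nrpb2-3. At the lower end, the defensin gene PDF1.2A (AT5G44420), a marker of jasmonate and ethylene signalling, stood at 346 ± 370.0 CPM in Col-0 and 1.43 ± 1.83 CPM in nrpb2-3 (−7.92 ± 1.52, adjusted p = 0.0048). Its paralog PDF1.3 (AT2G26010) was at −10.05 ± 1.65. The SD of PDF1.2A in Col-0 was as large as its mean, since its 3 Col-0 libraries held 752, 258 and 27.4 CPM. The fold change of PDF1.2A was −6.64 without Col-0 replicate 1 and −9.76 without nrpb2-3 replicate 2 (PDF1.3: −8.11 and −10.93). In all, 3238 genes were higher and 3097 lower of 20471 tested (edgeR, adjusted p under 0.05), 30.9% of those tested, and 1364 and 763 of them by at least 2-fold. The split depended on the scale: with library totals and no normalization factor the calls were 10688 higher and 758 lower, and the median log2 fold change of all genes moved from 0.05 to 0.59. Every direction given for nrpb2-3 is thus relative to the bulk of its transcripts. On that scale photosynthesis genes stayed lower (median −0.65, 21 of 27 called). Without nrpb2-3 replicate 3 the higher calls fell to 1996, the only library whose removal moved either count by more than 1.5 times. With the replicate number as a block the calls were 4083 higher and 3840 lower.

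The comparison of ssrp1-2 with Col-0 addressed the transcripts that depend on the SSRP1 subunit of FACT. Genes that build flowers were higher in these seedlings. SEP2 (AT3G02310) rose from 0.0389 ± 0.0447 to 3.55 ± 1.26 CPM (log2 fold change 6.44 ± 0.65, adjusted p = 0.00048), SEP3 (AT1G24260) from 1.34 ± 0.491 to 8.26 ± 1.33 CPM (2.63 ± 0.28, adjusted p = 0.00078). AP3 (AT3G54340) rose from 0.114 ± 0.117 to 2.79 ± 0.725 CPM (4.59 ± 0.58, adjusted p = 0.0034). The SEP genes act in all whorls of the flower and AP3 specifies petals and stamens. AP1 (2.83 ± 0.35), its close relative FUL (AT5G60910, 1.69 ± 0.22) and the age-pathway activator SPL9 (AT2G42200, 0.96 ± 0.12) rose too. So did STM (AT1G62360, 1.82 ± 0.22), which maintains the shoot meristem, and HSP18.2 (AT5G59720), a small heat shock protein gene (1.26 ± 0.19, adjusted p = 0.0092). Of 7 floral organ identity genes 4 were higher and 0 lower (5 and 0 adjusted over the list alone; median 2.45, list adjusted p = 1.7e-12, 0.018 with an estimated correlation). Of 7 shoot meristem genes 2 were higher (6 adjusted over the list alone; median 1.36, adjusted p = 8.8e-11, 0.045 with an estimated correlation). Of 11 floral promoters 3 were higher and 1 lower (6 and 1 adjusted over the list alone; median 0.73, adjusted p = 1.5e-06, 0.023 with an estimated correlation). The FLC clade list was lower (median −0.98, adjusted p = 8.0e-06, 0.045 with an estimated correlation), with 0 of 6 members called over all genes and 4 lower adjusted over the list alone. These were the 4 lists called under both forms of the list test, and FLC itself was low in both groups (0.562 ± 0.478 CPM in Col-0, 0.236 ± 0.206 CPM in ssrp1-2) and not called (−1.26 ± 0.86, adjusted p = 0.73). Leaving out Col-0 replicate 1 moved AP3 to 5.58 with its call kept, and left 1 count of SEP2 in Col-0, so no fold is given for it.

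A further 9 lists were called in ssrp1-2 with the preset correlation and not with an estimated one. Higher were microRNA targets (2 of 35 higher, 3 adjusted over the list alone, median 0.20, adjusted p = 8.0e-06, 0.12 with an estimated correlation), with the boundary gene CUC2 (AT5G53950) at 1.97 ± 0.29 (adjusted p = 0.0082, 8.3e-07 to 0.054 over its alternatives, the highest in a fit on the 6 libraries of these groups alone). RNA-directed DNA methylation was called higher as well (0 of 16, 4 adjusted over the list alone, median 0.35, adjusted p = 2.1e-05, 0.23 with an estimated correlation). Cell cycle genes (median 0.19, adjusted p = 0.0020, 0.56 with an estimated correlation) and flavonoid genes (3 higher adjusted over the list alone, median 0.46, adjusted p = 0.012, 0.56) were also called higher. So were heat shock genes (1 of 17 higher, median 0.30, adjusted p = 0.015, 0.39) and microRNA biogenesis (median 0.15, adjusted p = 0.023, 0.51). Auxin genes (5 lower and 1 higher adjusted over the list alone, median −0.23, adjusted p = 0.011, 0.31 with an estimated correlation), abscisic acid and cold genes (1 lower adjusted over the list alone, median −0.35, adjusted p = 0.012, 0.51) and wounding and touch genes (median −0.65, adjusted p = 0.021, 0.64) were called lower. In these 3 lists, the cell cycle, the flavonoid and the microRNA biogenesis lists 0 members were called over all genes. Of these 9 calls, 7 ended when 1 of the 6 libraries compared was left out. Without Col-0 replicate 1 the calls ended for abscisic acid and cold (adjusted p = 0.20), cell cycle (0.62), microRNA biogenesis (0.83) and wounding (0.14). Without Col-0 replicate 2 they ended for wounding (0.62), auxin (0.058), flavonoids (0.16) and heat shock (0.17). Without Col-0 replicate 3 they ended for heat shock (0.48), which was also lost when genes with low counts were kept (0.071). Without ssrp1-2 replicate 1 they ended for abscisic acid and cold (0.052), microRNA biogenesis (0.052) and wounding (0.29). Without ssrp1-2 replicate 2 they ended for flavonoids (0.23) and heat shock (0.21). Without ssrp1-2 replicate 3 they ended for abscisic acid and cold (0.21), microRNA biogenesis (0.062), wounding (0.22), flavonoids (0.052) and heat shock (0.057). Photosynthesis (median −0.14, adjusted p = 0.057) and DNA damage (median 0.11, adjusted p = 0.057) were not called. Neither were the H2A.Z and SWR1 list (median 0.08, adjusted p = 0.43, 0 of 13 members called; HTA11 0.16 ± 0.16, adjusted p = 0.84) and the remaining 8 lists. Those were the clock (adjusted p = 0.14), core histones (0.16, median −0.04, or 0.01 with library totals), elongation factors (0.18), ribosome biogenesis (0.42), jasmonate (0.55) and root markers (0.64), with salicylic acid (0.75, median −0.11 and mean 0.03) and Pol II subunits (0.89, median −0.08 and mean 0.03). Photosynthesis was called lower with low counts kept (adjusted p = 0.039) and without Col-0 replicate 3 (0.013) or ssrp1-2 replicate 1 (0.0068). DNA damage was called higher without Col-0 replicate 3 (0.040) or ssrp1-2 replicate 2 (0.034), and core histones lower without Col-0 replicate 1 (0.035) or ssrp1-2 replicate 1 (0.015). Ribosome biogenesis was called lower without Col-0 replicate 1 (0.027) and higher without Col-0 replicate 3 (0.0010). Jasmonate was called higher without ssrp1-2 replicate 1 (0.026) and lower without ssrp1-2 replicate 2 (0.0028).

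Among single genes, RXF26 (AT1G58430) had 0 counts in Col-0 and 3.79 ± 1.69 CPM in ssrp1-2, at least 136-fold higher. MLP328 (AT2G01520), of the major latex protein family, stood 206 (95% counting interval 36.5 to 8157) times higher. Genes at the lower end were fewer and less stable. GRP3S (AT2G05380), a glycine-rich protein gene, fell from 62.4 ± 12.2 to 20.7 ± 4.07 CPM (−1.59 ± 0.25, adjusted p = 0.015). ACS4 (AT2G22810), an enzyme of ethylene synthesis, fell from 5.71 ± 2.73 to 1.46 ± 0.367 CPM (−1.96 ± 0.37, adjusted p = 0.032). GRP3S lost its call without Col-0 replicate 2 (adjusted p = 0.063), Col-0 replicate 3 (0.060), ssrp1-2 replicate 1 (0.072) or ssrp1-2 replicate 3 (0.077). ACS4 lost it without Col-0 replicate 1 (0.14), Col-0 replicate 3 (0.060) or any one ssrp1-2 library (0.099, 0.13 and 0.10), and in a fit on the 6 libraries alone (0.12). In all, 93 genes were higher and 21 lower of 20471 tested (edgeR), 78 and 11 of them by at least 2-fold, and 1919 had an unadjusted p under 0.05. DESeq2 called 210 higher and 79 lower, and a fit on the 6 libraries of these groups alone called 34 and 3. Leaving out any one of those 6 libraries gave 38 to 53 higher and 1 to 16 lower. Of the 32 named genes that were called here, 10 were called under every alternative run.

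**Figure D2:**
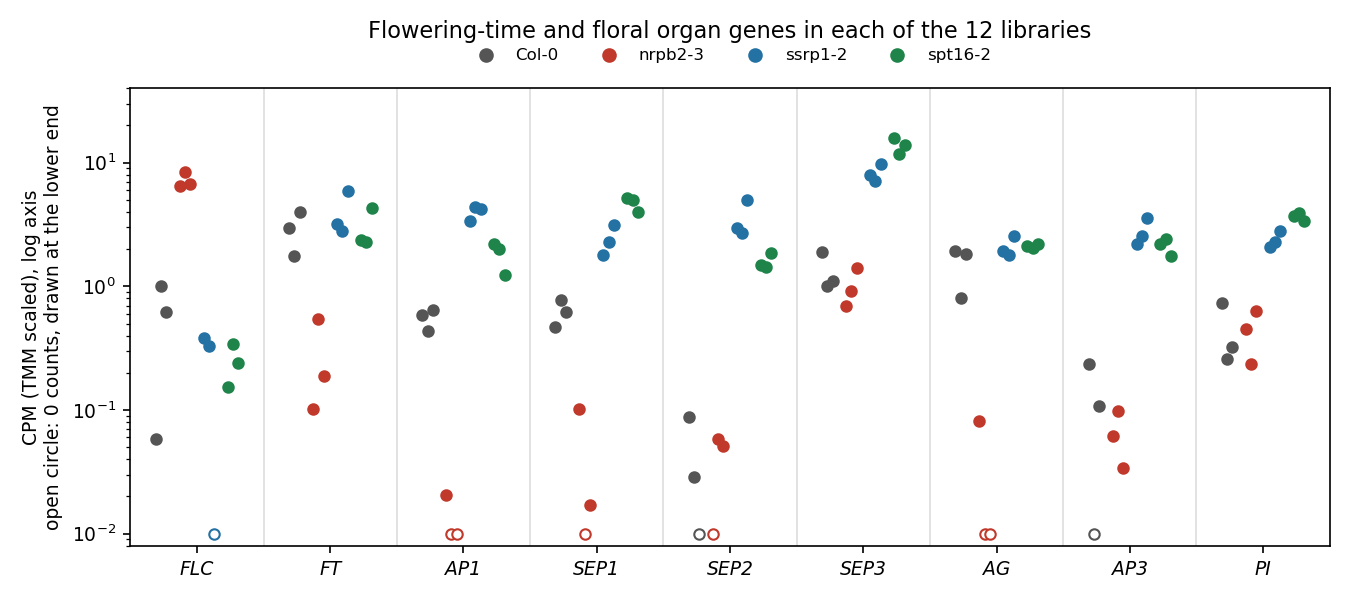
Transcript levels of FLC, FT and 7 floral MADS-box genes in each of the 12 libraries, in scaled CPM on a log axis, with open circles at the bottom for libraries with 0 counts. FLC is highest in nrpb2-3 (7.21 ± 1.06 CPM, mean ± SD, n = 3) and SEP2 highest in ssrp1-2 (3.55 ± 1.26 CPM).

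The comparison of spt16-2 with Col-0 addressed the same question for the SPT16 subunit, with the library labelled spt16-2 replicate 2 among its 3 mutant libraries. Floral organ identity genes were higher here as well. SEP3 rose from 1.34 ± 0.491 to 13.9 ± 2.00 CPM (log2 fold change 3.37 ± 0.29, adjusted p = 0.00015), SEP2 to 1.59 ± 0.228 CPM (5.28 ± 0.66, adjusted p = 0.0031) and AP3 to 2.13 ± 0.334 CPM (adjusted p = 0.0049). PI (AT5G20240), the partner of AP3, rose from 0.438 ± 0.256 to 3.66 ± 0.291 CPM (3.06 ± 0.40, adjusted p = 0.0039). Genes of the DNA damage response rose with them, NAC044 from 0.866 ± 0.151 to 4.98 ± 0.695 CPM (2.52 ± 0.23, adjusted p = 0.00023) and GMI1 from 1.94 ± 0.766 to 8.90 ± 2.62 CPM (adjusted p = 0.0039). HSP18.2 rose too (1.41 ± 0.19). Of 7 floral organ identity genes 5 were higher and 0 lower (6 and 0 adjusted over the list alone; median 3.06, list adjusted p = 6.3e-16, 0.0084 with an estimated correlation). Of 10 DNA damage genes 2 were higher (7 adjusted over the list alone; median 0.65, list adjusted p = 2.4e-12, 0.0084 with an estimated correlation). These 2 lists were called under both forms of the list test. Shoot meristem (0 of 7 called, 4 higher adjusted over the list alone, median 1.09, adjusted p = 5.9e-07, 0.11 with an estimated correlation) was called higher with the preset correlation alone. So were floral promoters (1 of 11 higher, 4 adjusted over the list alone, median 0.53, adjusted p = 0.00030, 0.067 with an estimated correlation). Without Col-0 replicate 1 the fold change of AP3 was 5.19.

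The preset correlation gave 13 further list calls in spt16-2, none of which held with an estimated one. Called higher were RNA-directed DNA methylation (median 0.28, adjusted p = 2.2e-05, 0.24 with an estimated correlation), cell cycle (0.16, 0.0090, 0.59), microRNA biogenesis (0.21, 0.024, 0.44), each with its median and both adjusted p-values in that order. So were heat shock (0.16, 0.032, 0.42), microRNA targets (0.08, 0.036, 0.44) and elongation factors (0.09, 0.049, 0.38). Called lower, in the same order, were abscisic acid and cold (−0.44, 0.00016, 0.33), jasmonate (−0.47, 0.0014, 0.44), photosynthesis (−0.19, 0.0022, 0.59) and auxin (−0.27, 0.0039, 0.24). Further lists called lower were core histones (−0.07, 0.032, 0.65), salicylic acid defence (−0.34, 0.032, 0.53) and the FLC clade (−0.45, 0.049, 0.38). Over all genes, HSP18.2 was the single called member of these 13 lists (adjusted over the list alone, 2 microRNA targets were higher and 1 abscisic acid and cold gene lower). With library totals as the scale the histone median turned from −0.07 to 0.02. Without the library labelled spt16-2 replicate 2 the calls ended for photosynthesis (adjusted p = 0.28), cell cycle (0.33), core histones (0.23, now on the higher side), microRNA biogenesis (0.057) and elongation (0.057). Without Col-0 replicate 1 they ended for photosynthesis (0.097), cell cycle (0.86, now on the lower side), microRNA biogenesis (0.79), salicylic acid (0.067), microRNA targets (0.20), the FLC clade (0.14) and elongation (0.27). Without Col-0 replicate 2 they ended for heat shock (0.061), histones (0.057), salicylic acid (0.12), microRNA targets (0.21) and elongation (0.068). Without Col-0 replicate 3 they ended for heat shock (0.23), histones (0.36) and the FLC clade (0.12). Without spt16-2 replicate 1 they ended for heat shock (0.14), salicylic acid (0.15), the FLC clade (0.28) and elongation (0.13). Without spt16-2 replicate 3 they ended for microRNA biogenesis (0.058), salicylic acid (0.16), microRNA targets (0.22), the FLC clade (0.058) and elongation (0.16). With low counts kept, microRNA targets (0.10) and elongation (0.17) were lost, and with median-of-ratios size factors the FLC clade (0.053) and elongation (0.055). Clock genes (median −0.10, adjusted p = 0.073) and wounding genes (−0.47, 0.30) were not called without a replicate block and were called lower with one (0.0496 and 0.017), though library totals turned the clock median to 0.02. Clock genes were also called lower with low counts kept (0.047), wounding genes without Col-0 replicate 3 (0.00022), and both without the library labelled spt16-2 replicate 2 (0.025 and 0.028), while ribosome biogenesis was called higher without Col-0 replicate 3 (0.00022). The H2A.Z and SWR1 list was not called (median 0.07, adjusted p = 0.31; HTA11 −0.14 ± 0.16, adjusted p = 0.90). Neither were flavonoids (0.48), ribosome biogenesis (0.17), Pol II subunits (0.90, median −0.01 and mean 0.01) and root markers (0.90, median 0.03 and mean −0.43).

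AT4G18900 had 0 counts in Col-0 and 2.16 ± 0.601 CPM in spt16-2, at least 75.6-fold higher. AT2G18193 rose from 0.426 ± 0.181 to 8.78 ± 1.34 CPM (4.36 ± 0.40, adjusted p = 0.00023). At the lower end, HB5 (AT5G65310), a homeodomain-leucine zipper gene, fell from 93.1 ± 19.1 to 41.3 ± 7.54 CPM (−1.17 ± 0.20, adjusted p = 0.025). The call was lost without Col-0 replicate 1 (0.12), Col-0 replicate 3 (0.087), spt16-2 replicate 1 (0.080), the library labelled spt16-2 replicate 2 (0.12) or spt16-2 replicate 3 (0.069), and in a fit on the 6 libraries alone (0.062). In all, 77 genes were higher and 9 lower of 20471 tested (edgeR), 74 and 5 of them by at least 2-fold, and 1679 had an unadjusted p under 0.05. With the replicate number as a block the calls were 92 higher and 25 lower, DESeq2 called 182 and 58, limma-trend on the authors' scaled TPM 51 and 5, and a fit on the 6 libraries alone 42 and 0. Leaving out any one of the 6 libraries gave 31 to 37 higher and 0 to 5 lower, and without the library labelled spt16-2 replicate 2 the counts were 35 and 1. Of the 28 named genes that were called here, 11 were called under every alternative run.

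**Figure D3:**
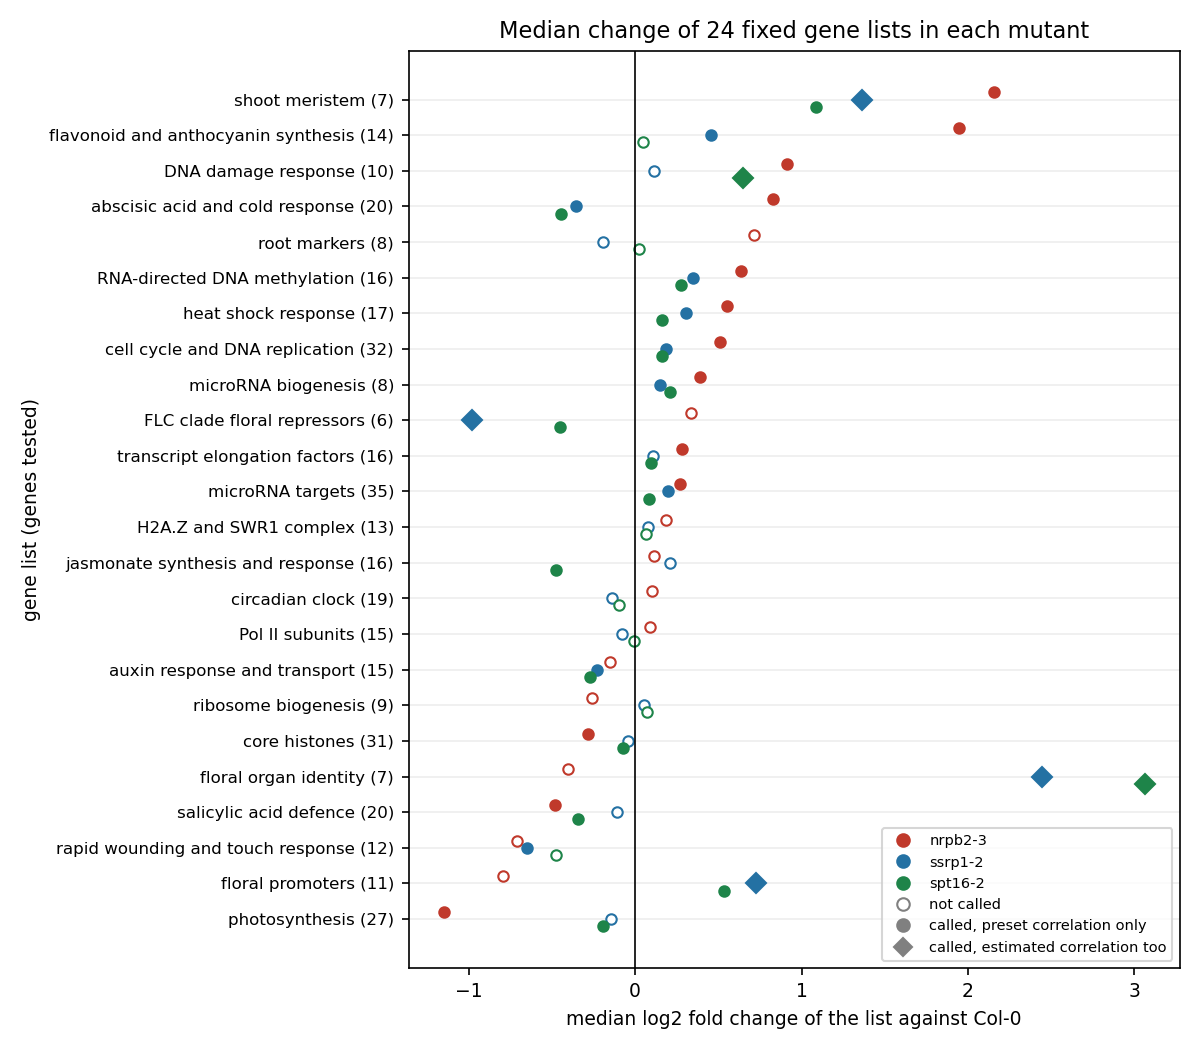
Median log2 fold change against Col-0 of the tested members of each of 24 gene lists in nrpb2-3, ssrp1-2 and spt16-2, where filled points are lists called by the list test at an adjusted p under 0.05 and diamonds are lists also called with an estimated correlation. Floral organ identity lies at 2.45 in ssrp1-2 and 3.06 in spt16-2 and at −0.40 in nrpb2-3, where it was not called and where scaling by library totals moves it to 0.17.

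The overlap of the mutants addressed how much of each response is common to them. In both FACT mutants 35 genes were higher and 4 lower, where independent sets of this size would share 0.350 and 0.00923. Of the genes called in both, 0 went in opposite directions (0.120 by chance). For the difference itself 619 genes had an unadjusted p under 0.05, a smaller share of those tested than the 0.05 that no difference would give. A share that low points to a conservative test for this pair and does not show that the mutants are alike. SEP2, SEP3, AP3 and HSP18.2 were among those higher in both. The fold changes correlated across genes with r = 0.71 and a covariance of 0.236, against r = 0.50 and 0.0550 for 20 simulations of unchanged groups that share the Col-0 libraries, a difference in covariance of 0.181. The Pol II mutant shared 52 higher and 9 lower genes with ssrp1-2 (14.7 and 3.18 by chance; 12 went in opposite directions, fewer than chance gives). It shared 46 higher and 5 lower genes with spt16-2 (12.2 and 1.36 by chance, with 4 in opposite directions against 13.1). The differences in covariance from the simulated values were 0.185 and 0.199. Their r of 0.42 and 0.42 lay below all 20 simulated values (0.49 to 0.53 and 0.49 to 0.53). In all 3 mutants 19 genes were higher and 3 lower. Among the lower ones, AT4G21445 stood at 16.1 ± 2.83 CPM in Col-0, a mean of 10.5 in nrpb2-3, 9.03 ± 0.573 in ssrp1-2 and 8.77 ± 1.26 CPM in spt16-2. Its call was lost in ssrp1-2 and in spt16-2 without any one of the 6 libraries compared and in a fit on those 6 alone, with adjusted p-values up to 0.16 and 0.16. Among the higher ones, the non-coding RNA AT1G67105 stood at 0.314 ± 0.135 CPM in Col-0, 83.0 ± 27.2 in nrpb2-3, 8.30 ± 4.88 in ssrp1-2 and 5.54 ± 2.87 CPM in spt16-2. In ssrp1-2 its call was lost without Col-0 replicate 1 (adjusted p = 0.073), 2 (0.083) or 3 (0.063), and its log2 fold change moved from 4.72 to 4.13 without ssrp1-2 replicate 1. In spt16-2 it was lost without Col-0 replicate 1 (0.13), 2 (0.14) or 3 (0.13), spt16-2 replicate 1 (0.069), the library labelled spt16-2 replicate 2 (0.056) or spt16-2 replicate 3 (0.069), and with low counts kept (0.052). With 3 controls the Col-0 libraries could not be divided between the comparisons, so the part that shared controls add to the covariance was taken from the simulations alone. In these 0 genes were called alike, a count all but fixed beforehand, since unchanged groups give almost no calls. It does not measure what shared controls add to the shared calls. The simulated genes vary independently, so shifts of a whole Col-0 library may add more covariance than simulated. Leaving out any one library of the groups involved gave 14 to 26 shared genes for the FACT mutants (lowest without spt16-2 replicate 1, and 17 without the library labelled spt16-2 replicate 2). The range was 21 to 57 for nrpb2-3 with ssrp1-2 (lowest without Col-0 replicate 1) and 20 to 48 for nrpb2-3 with spt16-2 (lowest without the library labelled spt16-2 replicate 2).

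The direct comparison of spt16-2 with ssrp1-2 tested where the FACT mutants differ. SSRP1 was higher in spt16-2 (1.42 ± 0.11, adjusted p = 0.00014), as it was lowered in ssrp1-2. SPT16 did not pass the test (−1.10 ± 0.22, adjusted p = 0.17, or 0.0025 without the library labelled spt16-2 replicate 2, within 0.0013 to 0.71 over its alternatives). NAC044 was higher in spt16-2 (4.98 ± 0.695 against 1.69 ± 0.194 CPM, 1.56 ± 0.22, adjusted p = 0.016) and so was AT2G18193 (8.78 ± 1.34 against 0.911 ± 0.288 CPM, 3.27 ± 0.37, adjusted p = 0.0037). The DNA damage list was higher in spt16-2 (median 0.56, adjusted p = 4.9e-15, 0.0080 with an estimated correlation), with 1 of 10 members called and 4 adjusted over the list alone. The FLC clade (2 higher adjusted over the list alone, median 0.30, adjusted p = 0.00039, 0.16 with an estimated correlation) and floral organ identity (2 higher and 1 lower adjusted over the list alone, median 0.62, 0.037, 0.42) were called higher with the preset correlation alone. Called lower in the same way were jasmonate (−0.70, 1.9e-07, 0.34), microRNA targets (−0.10, 0.00034, 0.27) and shoot meristem (−0.33, 0.00034, 0.28). So were floral promoters (−0.37, 0.0017, 0.16), flavonoids (−0.37, 0.0057, 0.75) and salicylic acid defence (−0.14, 0.017, 0.75). Each of these 8 lists had 0 members called over all genes. None of the other 15 lists was called. In 5 of them the median and the mean had different signs, namely auxin (0.09 and −0.01), heat shock (0.06 and −0.05), Pol II (0.05 and −0.02), root markers (0.05 and −0.07) and RNA-directed DNA methylation (0.00 and −0.01). Without ssrp1-2 replicate 2 the calls ended for jasmonate (adjusted p = 0.49), flavonoids (0.65), salicylic acid (0.80) and floral organ identity (0.36). Without ssrp1-2 replicate 3 they ended for floral promoters (0.074), flavonoids (0.059) and salicylic acid (0.085). Without ssrp1-2 replicate 1 they ended for floral organ identity (0.36). Without spt16-2 replicate 1 they ended for flavonoids (0.10), salicylic acid (0.23) and floral organ identity (0.13). Without the library labelled spt16-2 replicate 2 they ended for floral organ identity (0.070) and without spt16-2 replicate 3 for salicylic acid (0.19). With a replicate block floral organ identity was not called (0.056) and wounding genes were called higher in spt16-2 (0.0018, against 0.11 without it). Wounding genes were also called higher without ssrp1-2 replicate 2 (4.3e-05) or spt16-2 replicate 3 (6.5e-05). Called lower were abscisic acid and cold without ssrp1-2 replicate 1 (0.048) or 3 (0.016) or spt16-2 replicate 1 (0.014), photosynthesis without ssrp1-2 replicate 3 (0.026) or spt16-2 replicate 1 (0.0015), and cell cycle without the library labelled spt16-2 replicate 2 (0.0079). Core histones were called lower without spt16-2 replicate 1 (9.4e-05) and higher without the library labelled spt16-2 replicate 2 (0.00098). In all, 11 genes were higher and 3 lower (edgeR), 11 and 2 of them by at least 2-fold. Of 20471 tested, 619 had an unadjusted p under 0.05, a smaller share than the 0.05 that no difference would give. The test was thus conservative here, and its few calls do not show that the mutants are alike. A replicate block gave 13 and 7, DESeq2 34 and 15, and a fit on the 6 libraries alone 17 and 5. Leaving out any one of those 6 libraries gave 3 to 6 higher and 1 lower, and leaving out a Col-0 or nrpb2-3 library gave 7 to 13 and 2 to 6. Of single genes, NAC044 lost its call without ssrp1-2 replicate 1 (0.065), 2 (0.088) or 3 (0.12), the library labelled spt16-2 replicate 2 (0.074) or spt16-2 replicate 3 (0.077).

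The last comparison set nrpb2-3 against the mean of the FACT mutants, to test where a Pol II mutant and the chaperone mutants differ without use of the wild type. Flowering genes separated them. AP1 stood at 0.00683 CPM in nrpb2-3, 3.98 in ssrp1-2 and 1.81 in spt16-2, with a ratio of the FACT mutants to nrpb2-3 of 458 (95% counting interval 82.0 to 18131). SEP1 (AT5G15800), another SEP gene, was at 0.0398 ± 0.0549, 2.41 ± 0.687 and 4.73 ± 0.646 CPM (−6.36 ± 0.54, adjusted p = 5.5e-06). FUL differed in the same direction (−2.24 ± 0.21, adjusted p = 1.2e-05). FLC went the other way (4.89 ± 0.61, adjusted p = 0.00026), and with it MAF1 (AT1G77080, 0.88 ± 0.12), MAF2 (AT5G65050, 0.72 ± 0.14) and MAF3 (AT5G65060, 0.70 ± 0.16) of its clade. Of 7 floral organ identity genes 6 were lower in nrpb2-3 (median −5.20, list adjusted p = 3.1e-05, 0.14 with an estimated correlation). Of 11 floral promoters 7 were lower and 1 higher (9 and 1 adjusted over the list alone; median −1.56, 4.0e-05, 0.087 with an estimated correlation). Of 6 FLC clade genes 4 were higher (5 adjusted over the list alone; median 0.80, 0.0033, 0.30 with an estimated correlation). Photosynthesis was lower in nrpb2-3 (24 of 27 lower, 27 adjusted over the list alone; 7.5e-12, 0.42 with an estimated correlation), and stayed lower with library totals as the scale (median −0.57). Abscisic acid and cold genes (13 of 20 higher, 13 adjusted over the list alone; mean 1.22, 1.4e-06, 0.30 with an estimated correlation) were higher in nrpb2-3, with RD29A at 1.90 ± 0.11 and the cold-induced COR15A (AT2G42540) at 2.00 ± 0.19. Flavonoid genes (10 of 14 higher and 1 lower; median 1.47, 1.4e-05, 0.42 with an estimated correlation) were higher in nrpb2-3, with the anthocyanin regulator PAP1 (AT1G56650) at 3.00 ± 0.34. Cell cycle (10 of 32 higher and 1 lower; median 0.27, 0.022, 0.61 with an estimated correlation) was called higher by a narrower margin. So was RNA-directed DNA methylation (6 of 16 higher, 9 adjusted over the list alone; median 0.37, 0.043, 0.61 with an estimated correlation). The cell cycle call ended without nrpb2-3 replicate 2 (adjusted p = 0.073) or 3 (0.091). The DNA methylation call ended with a replicate block (0.060) and without nrpb2-3 replicate 1 (0.085), nrpb2-3 replicate 2 (0.058), ssrp1-2 replicate 3 (0.065) or spt16-2 replicate 3 (0.061). Without nrpb2-3 replicate 1 the other nrpb2-3 libraries held at most 1 count of SEP1 and of AP1, so no fold is given. SSRP1 was higher in nrpb2-3 (0.96 ± 0.09, adjusted p = 1.9e-05), and SPT16 did not pass the test (0.45 ± 0.18, adjusted p = 0.080), but was called without the library labelled spt16-2 replicate 2 (0.0016, within 0.0016 to 0.21 over its alternatives). The H2A.Z and SWR1 list was not called (2 of 13 higher and 1 lower, median 0.13, adjusted p = 0.79), though HTA11 was lower in nrpb2-3 (−0.77 ± 0.15, adjusted p = 0.0017). Of the other lists not called, 2 of 31 core histones were higher and 9 lower, and 5 of 7 shoot meristem genes higher and 1 lower (adjusted p = 0.10 and 0.084). The medians of auxin (−0.01 to 0.42), jasmonate (−0.08 to 0.37) and core histones (−0.09 to 0.35) turned with library totals. So did those of wounding (−0.08 to 0.33), ribosome biogenesis (−0.27 to 0.18) and salicylic acid (−0.26 to 0.22). With low counts kept, DNA damage (0.028) and root markers (0.016) were called higher. DNA damage was also called higher without nrpb2-3 replicate 1 (0.022) or the library labelled spt16-2 replicate 2 (0.038), which also brought calls for shoot meristem (higher, 0.040) and core histones (lower, 0.012). Root markers were called higher without nrpb2-3 replicate 2 (0.0091), ssrp1-2 replicate 1 (0.027) or 2 (0.040), spt16-2 replicate 1 (0.033) or the library labelled spt16-2 replicate 2 (0.038). Salicylic acid was called lower without nrpb2-3 replicate 3 (0.013), ssrp1-2 replicate 1 (0.025) or spt16-2 replicate 1 (0.048), and ribosome biogenesis lower without spt16-2 replicate 1 (0.048). In all, 3198 genes were higher and 3070 lower (edgeR), 1075 and 671 of them by at least 2-fold. With library totals and no normalization factor the calls were 10675 and 905, with the median of all genes moved from 0.04 to 0.49. Without nrpb2-3 replicate 3 the higher calls fell to 1721. With the replicate number as a block, read as pairs here, the calls were 3983 higher and 3839 lower.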

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

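The tests on the SPT16 level, the length tests on the FACT mutants alone (both kinds of splits) and on single mutants without Col-0 replicate 1, and the test on a few genes taking most of the counts were chosen after the result was seen. Against Col-0, 13 genes were called in opposite directions in nrpb2-3 and in a FACT mutant (12 with ssrp1-2 and 4 with spt16-2), fewer for each mutant than independent sets would give (13.1 for spt16-2). Their fitted log2 differences between nrpb2-3 and the mean of the FACT mutants are given as sizes, since genes chosen this way all but have to differ there. Lower in nrpb2-3 were AP1 (1 count there, −8.17, adjusted p = 1.3e-06), AT5G44630 (1 count there, −6.77), SEP1 (−6.36), SWEET10 (AT5G50790, −5.73), CYP706A3 (AT5G44620, −4.71), ASE3 (AT4G38880, −4.70), AT4G19430 (−3.06), AT5G01320 (−2.29), FUL (−2.24) and AT1G12570 (−1.28). The fitted sizes of AP1 and AT5G44630 rest on 1 count in nrpb2-3 and are uncertain (AP1: −9.77 to −1.74 over its alternatives). Higher were SSRP1 (0.96), which is the mutated gene of ssrp1-2, AT4G16750 (1.55) and AT1G52100 (5.58, adjusted p = 5.6e-09). The adjusted p of the 13 differences was at most 0.00018, and those not in the report were chosen after their values were seen. No technical explanation was tested for this set, and the genotype stays open as its source.

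The first pattern weighed is the SPT16 level of the library labelled spt16-2 replicate 2. Of the 35 genes called without this library, 35 lay outside the Col-0 range in it in the same direction, with a median response of 0.950 of that of the other spt16-2 libraries (quartiles 0.837 to 1.05), against −0.0624 for SPT16 itself. That argues against a Col-0 library under a wrong label, which would leave all these genes near the Col-0 level. It argues less strongly against Col-0 RNA mixed into the library. On the log scale used, a mix lowers the response of strongly raised genes less than that of SPT16. What sets SPT16 apart from the other genes in this library stays open, and no biological explanation was tested.

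The second pattern is that fold changes against Col-0 rose with transcript length, with a rank correlation across 14509 genes of 0.36 in nrpb2-3, 0.32 in ssrp1-2 and 0.40 in spt16-2. Single libraries that differ in length bias were argued against for the mutants together (exact permutation p = 0.0455, 220 splits, 2-sided), a result that rests on nrpb2-3, but not for the FACT mutants alone (exact permutation p = 0.131, 84 splits, 2-sided), where such a bias may account for the trend. Each of the 6 FACT mutant libraries lay above the Col-0 library of its replicate number, but splits within the numbers did not exclude it either (exact permutation p = 0.148, 27 splits, 2-sided). Deviations of spt16-2 replicates 1, 2 and 3 from the mean of all libraries correlated with length at −0.28, 0.31 and −0.13. Those of the Col-0 libraries did so at −0.38, −0.23 and −0.20. The trend in spt16-2 thus rests mostly on the library labelled spt16-2 replicate 2. A trend with expression was argued against, since the smallest correlation was 0.315 after its removal. Col-0 replicate 1 alone was argued against as the source in nrpb2-3 and in spt16-2, where the correlation without it was 0.311 and 0.280. In ssrp1-2 it cannot be told apart, since the correlation there, 0.183, lay between the bounds of 0.1 and 0.2 set beforehand. The genotype itself stays open.

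The third pattern is the lower level of photosynthesis genes in nrpb2-3. By the prediction written beforehand, a lower level of all abundant transcripts was argued against. Of 10000 random lists matched in expression, 0.05% had a median as low (−0.95 for the random lists against −1.15). Their genes were drawn singly, though, while members of this list vary together (estimated correlation 0.82). The random lists thus spread too little, and the test does not decide it. The random lists were themselves low, so most of the size of the fall is shared with transcripts outside the list that are as abundant. These may hold other photosynthesis genes, since only the list members were left out. A few genes taking most of the counts would lower the share of the other genes, and was argued against by the genes outside the list, whose median log2 ratio to Col-0 with library totals as the scale was 0.46 to 0.81 in the nrpb2-3 libraries. Scaling by genes other than the 100 most abundant, the test written beforehand, hardly moved the list median (to −1.16) and decides nothing. The nrpb2-3 replicate 3 library alone was argued against by 23 of the 25 members called lower with all libraries, which were also called lower without it (median −0.89). Reads shared between paralogs were not tested, so the Pol II mutation is one candidate explanation among those left open.

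Other splits of the libraries tested whether the grouping matters. For each comparison of 3 with 3 libraries the 10 splits are too few for a share under 0.05. The genes called were 6335 for the real split and 0 for the highest other split in nrpb2-3 against Col-0, 114 and 0 in ssrp1-2, 86 and 3 in spt16-2, and 14 and 0 in spt16-2 against ssrp1-2, so 1 of 10 splits, the real one, gave as many in each. For lists they were 13 and 11, 13 and 12, 17 and 14 (again 1 of 10 splits each), and 9 and 10 in spt16-2 against ssrp1-2, where 3 of 10 splits gave as many. The other splits called a median of 8, 10, 7 and 6 lists. With the preset correlation many lists were thus called under other groupings too, though these keep part of any real difference. In nrpb2-3 against the pooled FACT mutants, 1 of 84 splits, the real one, gave as many genes (highest other 8), the smallest share possible. It gave 6501 genes in a fit that pools the FACT mutants, against 6268 in the report. That argues against a random grouping of the libraries, but cannot tell the genotype from anything else that the nrpb2-3 samples share. For lists, 35 of 84 splits gave as many (8, highest other 12), so a random grouping stays possible there. Where the numbers pair the libraries, the splits that part as many pairs gave at most 0 genes and 12 lists in spt16-2 against Col-0, 0 and 9 in spt16-2 against ssrp1-2, and 8 and 12 in the pooled comparison.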

How the results depend on the processing

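Removal of the length trend and scaling by library totals were tests chosen after the result was seen. No called named gene was called in the other direction under any alternative run, but library totals took HTB11 (AT3G46030) in nrpb2-3 from −0.53 to 0.01 and EBP1 (AT3G51800) against the FACT mean from −0.40 to 0.05, neither called there. Some lists changed direction: cell cycle and core histones in spt16-2, ribosome biogenesis and jasmonate in ssrp1-2 and core histones in spt16-2 against ssrp1-2 with 1 library left out, and the medians given in the report with library totals. Counts and correlations given here moved, and the cause was not tested, except that a fold threshold can only leave fewer calls. At these depths changes of 1.5-fold were mostly missed on simulated data in which few genes changed, unlike in nrpb2-3. Gene counts are given as higher and lower. With a fold threshold of 2, nrpb2-3 kept 1364 and 763 calls, nrpb2-3 against the FACT mean 1075 and 671, ssrp1-2 11 lower and spt16-2 5 lower. Library totals gave 10688 and 758 in nrpb2-3, 10675 and 905 against the FACT mean, and 8, 3 and 1 lower in ssrp1-2, spt16-2 and spt16-2 against ssrp1-2. DESeq2, which made more false calls on simulated data, gave 210 and 79 in ssrp1-2, 182 and 58 in spt16-2, 34 and 15 in spt16-2 against ssrp1-2, and 118, 167 and 137 shared genes (ssrp1-2 with spt16-2, nrpb2-3 with ssrp1-2, nrpb2-3 with spt16-2), with r = 0.56 for the FACT pair. limma-trend on the authors' scaled TPM gave 13 lower in ssrp1-2, 51 and 5 in spt16-2, and 25 and 23 genes that spt16-2 shared with ssrp1-2 and nrpb2-3. The groups compared alone gave 34 and 3 in ssrp1-2, 42 and 0 in spt16-2, and 17 and 5 in spt16-2 against ssrp1-2. With no filter on low counts r of the FACT pair was 0.54. With the replicate block spt16-2 had 25 lower, and spt16-2 against ssrp1-2 had 7 lower. As a hint that numbers also matter where they were not read as pairs (11 of 12 libraries correlated best with their own number), the block gave 143 and 49 in ssrp1-2, 111 genes that nrpb2-3 and ssrp1-2 shared, and list calls for photosynthesis in ssrp1-2 (adjusted p = 0.040) and wounding in nrpb2-3 (0.042); beyond these and the list calls in the report it changed no list call. The estimated correlation left 0, 4, 2, 1 and 0 lists of 13, 13, 17, 9 and 8.

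Leaving out 1 library of the groups compared gave 1996 to 2812 and 2369 to 2924 calls in nrpb2-3, 38 to 53 and 1 to 16 in ssrp1-2, 31 to 37 and 0 to 5 in spt16-2, 3 to 6 and 1 in spt16-2 against ssrp1-2, and 1721 to 3060 and 2099 to 3192 against the FACT mean. Shared genes were 14 to 26 (r 0.62 to 0.77) for the FACT pair, 21 to 57 (r 0.37 to 0.52) for nrpb2-3 with ssrp1-2 and 20 to 48 (r 0.36 to 0.53) for nrpb2-3 with spt16-2. Lists were 11 to 14, 8 to 15, 10 to 16, 6 to 10 and 7 to 12. Of the named genes called, 58 of 98, 10 of 32, 11 of 28, 2 of 10 and 42 of 88 were called under every alternative run, in the order of the 5 comparisons. The fold threshold ended 31, 3, 4, 1 and 37 of these calls, removal of the length trend 15, 4, 1, 0 and 6, and library totals 11, 5, 6, 2 and 9.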

Other observations

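No test in this part was chosen after the result was seen, but both verdicts on the hypotheses were changed after it, as said at each. Of all 20471 tested genes, 3238 were higher in nrpb2-3 than in Col-0 and 3097 lower. Among genes that code for no protein, 31 of 198 lncRNAs were higher there, a share close to that of all genes, and 7 lower. Of 108 other non-coding RNAs 23 were higher and 10 lower, and of 26 microRNA loci 2 were higher and 8 lower. Of 65 snoRNAs, 15 were lower and 0 higher, and of 140 organelle genes 4 were higher and 17 lower. In ssrp1-2 and spt16-2 the lncRNA calls were 1 and 2, all lower, and 0 snoRNAs, microRNA loci or organelle genes were called. With 0.557% and 0.420% of all tested genes called there, 0 calls in classes this small say little. The strand setting and the handling of reads that map to several places are unknown, and both weigh on short and overlapping non-coding genes. The rise of fold changes with transcript length in nrpb2-3 may also weigh on short genes such as those of snoRNAs.

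One hypothesis was that lower FLC clade repressors go with the higher floral genes of the FACT mutants. The mean log2 CPM of the clade was 0.599 higher in the 3 Col-0 libraries than in the 6 FACT mutant libraries (exact permutation p = 0.0595, 84 splits, 2-sided). The groups overlapped by a single library, the one labelled spt16-2 replicate 2 (1.59 against 1.58 in the lowest Col-0 library). By the prediction written beforehand, any overlap with a p of 0.05 or more counted against the hypothesis, and it was first read so; this was changed to undecided after the value was seen, because the overlap is far smaller than the spread of the Col-0 libraries and a p that misses the threshold does not show that the groups are alike. The clade may thus take part, but these libraries do not decide it.

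A further hypothesis was that genes with little transcript in Col-0 rise more often in the FACT mutants than in nrpb2-3. It was tested as their share among the genes called higher. By number, more such genes were called higher in nrpb2-3 alone (652) than in a FACT mutant alone (34). Of 56 genes called higher in a FACT mutant and not in nrpb2-3, 34 were under 1 CPM in Col-0 (60.7%), against 652 of 3159 called in nrpb2-3 alone (20.6%; Fisher exact p = 1.3e-10, 2-sided). Among genes at least 4-fold higher the shares were 88.2% (30 of 34) and 82.3% (391 of 475; Fisher exact p = 0.486). The first comparison met the prediction written beforehand. The 4-fold comparison was written before its value was seen but was no part of that prediction, and it was given a say in the verdict only after both values were seen. The first difference may come from the larger folds that a comparison with few calls selects. The Fisher test also treats genes as independent. Read as a share, the hypothesis stays open.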
